A study of Homo sapiens with 28 samples.

How the data were processed

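The series labels describe 28 samples. RNA sequencing of total RNA covered H9 human embryonic stem cells at day 0 (4 libraries) and the cultures derived from them at day 4 (4), day 15 (4), day 25 (4) and day 35 (3), with 2 further day 15 libraries labelled CHD2 knockdown. Chromatin immunoprecipitation sequencing covered day 15 cells, with NKX2-1, IgG and input libraries. Per the labels' protocols, cells grew as embryoid bodies with SB431542, LDN193189, XAV939 and purmorphamine until day 15, and then with DAPT, cyclic AMP, ascorbic acid and BDNF. Groups were taken from the labels. No vector or non-targeting control group was used here, so the libraries labelled CHD2 knockdown were compared with the unperturbed day 15 libraries. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

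The deposited table held raw counts per gene, whole numbers that summed to between 15021340 and 22877090 per library. Per the submitters' processing notes the tools were STAR 2.4.2a, Subread, featureCounts 1.4.6 and edgeR for RNA and BWA 0.7.12-r1039 and MACS2 for chromatin, on build hg38; their settings and the role of each tool are not given in the sources used here. A deposited column of percent values, the GC content of each gene per the file headers, was not used in any test. Whether counting used the strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The peaks were deposited as coordinates alone. Whether they were called per library or on pooled libraries is not given in the sources used here, and with no score the peaks were not ranked. Column headers were matched to the labels by day; the 4 columns of the day 15 group say day 14 in their names, and libraries are named here by the number in their column header. Another 2 columns of per-sample counts, whose headers say non target control, matched no labelled sample and were not used, so controls that may belong to the knockdown are not part of that comparison. Entries naming no gene numbered 0.

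The table had 62704 entries. For 401 gene IDs the entry was repeated with identical counts in every library, and the 510 repeats were dropped, which left 62194 genes, 14494 of them without a count in the 21 libraries. Symbols were found for 54837 IDs (88.2%), and 1366 symbols belonged to more than 1 ID. Copies with the same symbol can share or lose reads, which is stated beside genes it concerns. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom 8.26 to 150.44), so none was counted as a repeat of another. A count of 0 was bounded by 3 counts over the group, which came to 0.035, 0.041, 0.037, 0.039 and 0.054 CPM for days 0, 4, 15, 25 and 35 and 0.082 CPM for the libraries labelled CHD2 knockdown. Where the lower group held 1 to 3 counts, the ratio of CPM is given with its 95% counting interval. Intervals and floors cover counting error only.

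Genes were tested with edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood test, TMM factors and edgeR's filter on low counts by group, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested and called below 0.05. Contrasts between days came from a fit over the 19 time course libraries (21312 genes, common biological coefficient of variation 25.3%, 14 residual degrees of freedom). The libraries labelled CHD2 knockdown were fitted with the 4 day 15 libraries alone (19174 genes, 24.6%, 4 residual degrees of freedom). Fixed gene lists of pathways, regions and cell types (32 lists, 555 symbols) were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, over 160 list tests adjusted together, again with an estimated correlation, and with fry. With the preset correlation 77 of the 160 were called. With an estimated correlation none was called (lowest adjusted p 0.184), with 20 at an unadjusted p below 0.05, while fry called 78 for a balance in 1 direction and 141 for change in either direction.

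Peaks were assigned to the nearest protein-coding gene span of the RefSeq annotation of the same build within 50 kb of the peak's midpoint. That table was read for gene spans alone, so spans replaced the transcription starts planned for this step, and exon, intron or UTR was not assigned. Peak genes were compared with called genes (of at least 2-fold change in the time course, of any size in the libraries labelled CHD2 knockdown) by Fisher's exact test (two-sided) over the tested protein-coding genes, adjusted over 8 tests, and with a logistic model holding log2 gene length, mean log-CPM and log10 distance between neighbouring genes. Correlations between the changes of the libraries labelled CHD2 knockdown and those from day 4 to day 15 used log2 CPM with a prior count of 2, 50 simulations of unchanged groups and 6 splits of the day 15 libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for peaks and plots.

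Genes are named by a rule. For each RNA comparison it took the 6 largest rises and 6 largest falls among called protein-coding genes with groups that did not overlap and a mean of at least 5 CPM in the higher group, up to 4 called members of each list with the largest changes together with any member called against the list's majority, and always a small set that includes CHD2, NKX2-1, LHX6, GAD1 and POU5F1. The text names part of that set, and some genes that the rule gave are not reported here. Of the 6 largest rises in the libraries labelled CHD2 knockdown, 2 are genes with several IDs in the copy-rich region of chromosome 6 and are not named. Peaks are named where they belong to list members or to CHD2 and NKX2-1; the genes with most peaks, the peak distances of genes without a peak, the 134 genes high at day 0 and the ribosomal protein genes were chosen after their values were seen.

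Groups, tests, gene lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, edgeR's RLE factors, no low-count filter, a stricter adjusted p of 0.01, a 2-fold minimum, fits over other sets of libraries, other peak distances and widths, and leaving out each library in turn. The fits added after the data were seen were those without libraries 19 and 20, with the 4 runs of consecutive library numbers as a batch term, and without genes that have several IDs or are switched on or off. Library deviations from their group means correlated with a median of 0.137 (-0.104 to 0.66, 36 pairs) within such a run against -0.04 between runs (108 pairs), and 16 of 19 libraries correlated best with their own run, a hint from the data and not part of the design. The labels give replicate numbers that the columns do not carry.

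The tests were checked on simulated counts drawn with the real library sizes, with 200 changed genes each. Every group was drawn from the real means of the earlier day (day 15 for the libraries labelled CHD2 knockdown), with a single spread per gene. With so few changed genes and equal spread, the shares of genes recovered and falsely called may not hold for the real contrasts. For day 4 against day 0 (18497 genes) 58% of genes changed 2-fold and 95% of those changed 4-fold were recovered, with 5% false calls. The same 3 values were 59, 89 and 6.3% for day 15 against day 4 (19463 genes), 64, 95 and 5.9% for day 25 against day 15 (19577 genes), 45, 89 and 4.3% for day 35 against day 25 (19805 genes), and 32, 85 and 6.4% for the libraries labelled CHD2 knockdown (18578 genes). For peaks over 15141 genes, a planted odds ratio of 2 was recovered with a median of 1.97 and p below 0.05 in 50 of 50 simulations, and a planted ratio of 1 gave a median of 1.01 and p below 0.05 in 5 of 50.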

Results

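Gene expression was measured by RNA sequencing of total RNA while H9 cells, an established human embryonic stem cell line, were turned into cells resembling those of the medial ganglionic eminence (MGE), the ventral forebrain region where many cortical interneurons arise. The undifferentiated cells (day 0), day 4, day 15 and day 25 were each represented by 4 libraries and day 35 by 3. A further 2 libraries at day 15 were labelled CHD2 knockdown. CHD2 encodes a chromatin remodeller of the CHD family. Total counts per library ran from 21035250 to 22229264 at day 0, 15021340 to 22877090 at day 4 and 17398773 to 22663047 at day 15. They ran from 18259565 to 20121760 at day 25, 16734545 to 19386515 at day 35, and 17971336 to 18693249 in the libraries labelled CHD2 knockdown. Binding of NKX2-1, a homeodomain transcription factor of the MGE, was mapped by chromatin immunoprecipitation sequencing at day 15 and was represented by a single list of 4867 peaks. Levels are given as CPM, mean ± SD, with n = 4 except day 35 (n = 3) and the libraries labelled CHD2 knockdown (n = 2). Log2 fold changes are given with their standard error (SE). For each gene said to have risen or fallen, every library of the higher group lay above every library of the lower group unless an overlap is stated.

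The time course addressed how gene expression changed as the cells were specified and differentiated. Of 21312 genes tested, 17649 changed over the 5 days (edgeR's quasi-likelihood test, adjusted p below 0.05). The day of highest mean expression was day 0 for 5680 of these genes (32.2%), day 4 for 3192 (18.1%), day 15 for 2393 (13.6%), day 25 for 1974 (11.2%) and day 35 for 4410 (25%). The first principal component of the 21 libraries held 44.7% of the variance and the second 20.9%. Consecutive steps called 10606 genes from day 0 to day 4, 7498 from day 4 to day 15, 3609 from day 15 to day 25 and 3232 from day 25 to day 35.

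**Figure D1:**
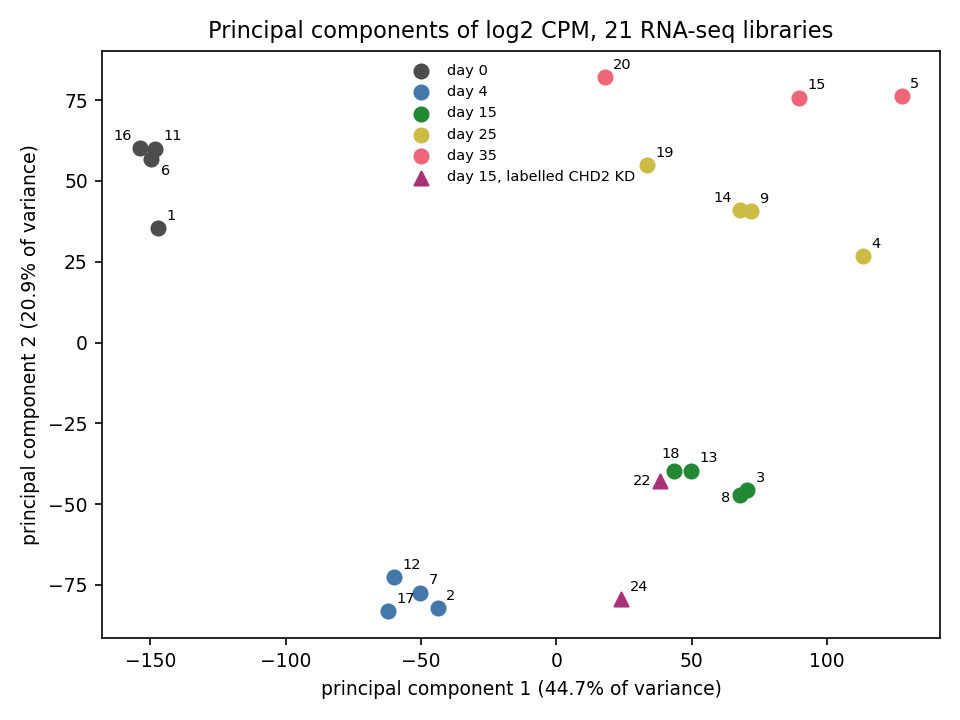
Principal component 1 (44.7% of the variance) against principal component 2 (20.9%) of log2 CPM for the 21 RNA libraries, each a point coloured by day and marked with its library number, with triangles for the 2 libraries labelled CHD2 knockdown. The libraries of days 0 and 4 form groups of their own, those of days 25 and 35 spread along component 1 with libraries 19 and 20 on the day 0 side of their days, and library 24 lies lower than the day 15 libraries on component 2.

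From day 0 to day 4 most genes of the pluripotency list fell and most genes of the early neuroectoderm list rose. NANOG, a pluripotency factor, fell from 85.2 ± 24.6 to 0.141 ± 0.136 CPM (log2 fold change -9.21, SE 1.16, adjusted p = 4.6e-06). TDGF1, a NODAL co-receptor, fell from 501 ± 38.3 to 2.6 ± 0.844 CPM. FOXD3, another factor of undifferentiated cells, fell from 51.4 ± 8.07 to 0.136 ± 0.0177 CPM. SIX3, a homeobox gene of the anterior neural plate, rose from 0.548 ± 0.14 to 110 ± 21.3 CPM (log2 fold change 7.65, SE 0.3, adjusted p = 5.1e-12), and the eye field and hypothalamic gene RAX rose from 1.17 ± 0.884 to 166 ± 11.2 CPM. SHH, the ventralizing morphogen, rose from 0.267 ± 0.129 to 46.3 ± 16.1 CPM (7.41, SE 0.77, adjusted p = 4.9e-07). PTCH1, its receptor and transcriptional target, rose from 35.2 ± 6.8 to 1790 ± 197 CPM. Per the labels the culture held purmorphamine, an agonist of the SHH pathway, in this period.

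Of the gene lists fixed for this step, 16 of 20 tested pluripotency genes fell and 4 did not pass the test (17 fell adjusted over the list alone; adjusted p = 0.554 with an estimated correlation). In the early neuroectoderm list 17 of 20 genes rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.214 with an estimated correlation). LHX5 rose from 1.65 ± 1.05 to 178 ± 50.4 CPM and SIX6 from 1.09 ± 0.527 to 95 ± 10.6 CPM, both homeobox genes of the anterior brain. Of 16 SHH pathway genes 12 rose and 4 did not pass the test, with the same count adjusted over the list alone (adjusted p = 0.184 with an estimated correlation). FOXA2, a floor plate factor, rose from 1.59 ± 0.631 to 180 ± 19.9 CPM. NKX2-2, a ventral factor under SHH control, was at 3.87 ± 2.24 CPM against no count at day 0, at least 113-fold higher against a floor of 3 counts over the group. The MGE list had 13 of 20 genes higher and 1 lower (13 and 2 adjusted over the list alone; adjusted p = 0.525 with an estimated correlation). NKX2-1 rose from 0.217 ± 0.108 to 45.8 ± 12.7 CPM (log2 fold change 7.69, SE 0.55, adjusted p = 6.1e-09). LHX6, a factor of postmitotic MGE interneurons, went the other way and fell from 1.92 ± 0.826 to 0.469 ± 0.163 CPM (-2.02, SE 0.49, adjusted p = 0.0024).

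Markers of other regions rose in the same step. In the midbrain, hindbrain and spinal cord list 11 of 14 genes rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.232 with an estimated correlation). The number that rose was 7 without library 7 and 7 without library 16. PAX5, a midbrain-hindbrain boundary gene, rose from 0.665 ± 0.166 to 38.7 ± 12.2 CPM. FOXB1, a forkhead gene of the caudal diencephalon and neural tube, rose from 9.36 ± 7.92 to 183 ± 30.1 CPM. The NOTCH list had 9 of 18 genes higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 0.384 with an estimated correlation). The NOTCH effector HES1 rose from 25.4 ± 4.43 to 187 ± 27 CPM and HEY1 from 2.62 ± 0.306 to 45.2 ± 19.8 CPM. Hypoxia and glycolysis genes moved down, 10 of 20 against 2 that rose (the same adjusted over the list alone; adjusted p = 0.622 with an estimated correlation). ADM, which encodes the vasodilator adrenomedullin, fell from 69.5 ± 3.59 to 10.5 ± 1.7 CPM. In the stress response list 8 of 15 genes fell and 2 rose (8 and 3 adjusted over the list alone; adjusted p = 0.525 with an estimated correlation). CHAC1, a glutathione-degrading enzyme of the integrated stress response, fell from 107 ± 63.3 to 3.32 ± 0.678 CPM. ASNS, asparagine synthetase, fell from 196 ± 39.3 to 26.4 ± 3.28 CPM.

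Among the largest rises were NKX2-8, a homeobox gene neighbouring NKX2-1, at 165 ± 24.1 CPM, a ratio of 7290 to the 2 counts at day 0 (counting interval 2020 to 60200), and HOPX at 30.1 ± 10.2 CPM, a ratio of 1350 to 2 counts (373 to 11100). LMX1A, a roof plate and midbrain floor plate factor, rose from 0.0762 ± 0.0497 to 56.8 ± 4.08 CPM (log2 fold change 9.43, SE 1.1, adjusted p = 1.9e-06). DBX1, a neural progenitor homeobox gene, rose from 0.165 ± 0.0935 to 85.8 ± 11.7 CPM. Of all 10606 genes called, 5343 rose and 5263 fell, and 6181 changed at least 2-fold. POU5F1, the stem cell factor OCT4, stood at 0.779 ± 0.112 CPM at day 0 and at 1 count in all at day 4. Its symbol is shared by 7 gene IDs, among which its reads could have been split or lost.

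Day 15 cells, compared with day 4, carried the transcripts of young neurons and of the MGE. STMN2, a microtubule regulator of growing axons, rose from 21.1 ± 10.6 to 671 ± 125 CPM (log2 fold change 4.99, SE 0.48, adjusted p = 4.5e-07). GAP43, a growth cone protein, rose from 3.29 ± 1.05 to 114 ± 15.3 CPM. DLX1, a homeobox gene of GABAergic progenitors, rose from 0.524 ± 0.289 to 21.8 ± 6.15 CPM (5.37, SE 0.49, adjusted p = 2.5e-07). NKX2-1 rose from 45.8 ± 12.7 to 316 ± 69.4 CPM (2.79, SE 0.37, adjusted p = 1.5e-05). LHX6 rose from 0.469 ± 0.163 to 4.86 ± 1.15 CPM (3.36, SE 0.48, adjusted p = 2.9e-05). FOXA2 fell from 180 ± 19.9 to 13.4 ± 4.03 CPM and FOXB1 from 183 ± 30.1 to 3.09 ± 0.645 CPM.

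Of 22 pan-neuronal genes 20 rose and 1 fell (21 and 1 adjusted over the list alone; adjusted p = 0.368 with an estimated correlation). ISL1, a LIM homeobox gene of several ventral neuron classes, rose from 0.297 ± 0.128 to 13.7 ± 2.25 CPM. RBFOX3, which encodes the nuclear antigen NeuN of mature neurons, fell from 6.03 ± 1.55 to 3.32 ± 0.344 CPM (log2 fold change -0.86, SE 0.25, adjusted p = 0.012). That call ended without library 17 (-0.68, adjusted p = 0.053). The MGE list had 16 of 20 genes higher and 1 lower (17 and 1 adjusted over the list alone; adjusted p = 0.368 with an estimated correlation). LHX8, a factor of subpallial cholinergic and MGE neurons, rose from 0.203 ± 0.0614 to 6.98 ± 4.48 CPM. DLX5, a relative of DLX1, rose from 0.0615 ± 0.0547 to 1.94 ± 0.453 CPM. SP9, a zinc finger factor of MGE progeny, rose from 0.434 ± 0.133 to 10.2 ± 1.9 CPM. NKX6-2, an MGE progenitor gene, fell from 19.6 ± 8.02 to 4.34 ± 0.339 CPM. In the synapse list 15 of 28 genes rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.525 with an estimated correlation). SNAP25, a vesicle fusion protein, rose from 0.496 ± 0.484 to 14.1 ± 4.94 CPM and the vesicle protein gene SYP from 6.85 ± 1.13 to 77.7 ± 13.3 CPM.

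In the cortical interneuron list 14 of 28 genes rose and 3 fell (16 and 4 adjusted over the list alone; adjusted p = 0.525 with an estimated correlation). SST, the somatostatin gene of an MGE-derived interneuron class, rose from 0.105 ± 0.0757 to 8.79 ± 6.38 CPM (log2 fold change 6.25, SE 0.8, adjusted p = 1.1e-05). CALB1, the calcium buffer calbindin, fell from 67.3 ± 20 to 1.85 ± 0.334 CPM. The p53 response list had 12 of 16 genes higher and 4 not called (13 higher adjusted over the list alone; adjusted p = 0.428 with an estimated correlation). The cell cycle inhibitor CDKN1A rose from 14.3 ± 2.39 to 118 ± 40.9 CPM (3.04, SE 0.44, adjusted p = 3.7e-05) and ZMAT3 from 18.2 ± 4.77 to 51.1 ± 15 CPM. SHH pathway genes were divided, with 4 of 16 higher and 7 lower, as they were adjusted over the list alone (adjusted p = 0.368 with an estimated correlation). SHH itself rose from 46.3 ± 16.1 to 224 ± 107 CPM (2.27, SE 0.52, adjusted p = 0.0024). The NOTCH list had 8 of 18 genes higher and 1 lower, also adjusted over the list alone (adjusted p = 0.385 with an estimated correlation), with DLL3 rising to 137 ± 12.7 CPM.

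Among the largest rises were FAM198B, from 0.0861 ± 0.0694 to 48.7 ± 31.7 CPM (log2 fold change 9.11, SE 0.92, adjusted p = 7.5e-07), and CORIN, a protease gene used as a floor plate marker, from 0.691 ± 0.241 to 123 ± 73.1 CPM. DDC, aromatic amino acid decarboxylase, rose from 0.231 ± 0.0922 to 41.2 ± 20.9 CPM and the adhesion gene CNTN6 from 0.287 ± 0.224 to 36.3 ± 12.9 CPM. Among the largest falls were GSC, an organizer homeobox gene, from 86.6 ± 17.6 to 0.349 ± 0.123 CPM (-7.95, SE 0.47, adjusted p = 2e-09), and VWF, the endothelial von Willebrand factor gene, from 88.3 ± 22.6 to 1.34 ± 1.17 CPM. DMRTA2 fell from 22.3 ± 6.95 to 0.322 ± 0.137 CPM. OTP, a hypothalamic homeobox gene, rose to 18.8 ± 2.92 CPM. In all, 4109 genes rose and 3389 fell, and 4248 changed at least 2-fold.

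Between day 15 and day 25 most genes of the mesenchyme and GABA receptor lists rose, and some genes of the SHH and NOTCH pathway lists fell. Per the labels this step followed a change of medium, in which DAPT, a gamma-secretase inhibitor that blocks NOTCH signalling, came in. COL1A1, a fibrillar collagen gene, rose from 3.55 ± 1.98 to 200 ± 241 CPM (log2 fold change 5.80, SE 0.77, adjusted p = 5.4e-05). GABRB1, a GABA-A receptor subunit gene, rose from 0.168 ± 0.0712 to 2.19 ± 0.454 CPM (3.67, SE 0.47, adjusted p = 3.6e-05). PTCH1 fell from 467 ± 50.8 to 134 ± 47.3 CPM (-1.80, SE 0.23, adjusted p = 2.7e-05). DLL4, a NOTCH ligand gene, fell from 11 ± 3.14 to 1.66 ± 0.278 CPM. LHX6 rose from 4.86 ± 1.15 to 15.7 ± 8.01 CPM (1.69, SE 0.39, adjusted p = 0.0055). GAD1, which encodes the GABA-synthesizing enzyme GAD67, rose from 7.01 ± 1.32 to 25 ± 10.5 CPM (1.83, SE 0.39, adjusted p = 0.0033).

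In the mesenchyme list 11 of 14 genes rose and 3 were not called (12 rose adjusted over the list alone; adjusted p = 0.184 with an estimated correlation). DCN, the proteoglycan decorin, rose from 0.106 ± 0.0186 to 3.3 ± 1.97 CPM. Of 13 GABA receptor subunit genes 8 rose and 5 were not called (9 rose adjusted over the list alone; adjusted p = 0.368 with an estimated correlation). The SHH pathway list had 7 of 16 genes lower and 9 not called, also adjusted over the list alone (adjusted p = 0.25 with an estimated correlation). CDON, a co-receptor gene, fell from 60.4 ± 10.1 to 23.7 ± 6.84 CPM. In the NOTCH list 5 of 18 fell and 1 rose (5 and 2 adjusted over the list alone; adjusted p = 0.368 with an estimated correlation). DLL3 fell from 137 ± 12.7 to 53.4 ± 11 CPM, while the ligand gene JAG1 rose from 61.5 ± 14.3 to 179 ± 90.7 CPM. Of 28 cortical interneuron genes 12 rose and 2 fell (14 and 4 adjusted over the list alone; adjusted p = 0.428 with an estimated correlation). NXPH1, a secreted neurexin ligand of interneurons, rose from 1.31 ± 0.766 to 23.6 ± 13.6 CPM (log2 fold change 4.18, SE 0.57, adjusted p = 7.2e-05). CALB1 rose from 1.85 ± 0.334 to 28 ± 10.2 CPM (3.91, SE 0.32, adjusted p = 2.8e-07).

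Parts of the astrocyte and stress response lists rose too. In the astrocyte list 6 of 12 genes rose and 6 were not called (8 rose adjusted over the list alone; adjusted p = 0.368 with an estimated correlation). The water channel gene AQP4 rose from 0.436 ± 0.285 to 5.91 ± 4.28 CPM and SPARCL1 from 5.32 ± 1.86 to 30.7 ± 13.5 CPM. The stress response list had 8 of 15 higher and 7 not called, also adjusted over the list alone (adjusted p = 0.428 with an estimated correlation). ASNS rose from 48.9 ± 6.76 to 135 ± 44 CPM (log2 fold change 1.46, SE 0.21, adjusted p = 8.9e-05). Of 17 replication-dependent histone genes 9 fell and 8 were not called (14 fell and 1 rose adjusted over the list alone; adjusted p = 0.428 with an estimated correlation). The number that fell was 3 without library 18 and 5 without library 4. HIST1H3D fell from 304 ± 56.3 to 161 ± 25.1 CPM.

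Some transcripts of the stem cell state rose again at low levels. In the pluripotency list 9 of 20 genes rose and 11 were not called (11 rose adjusted over the list alone; adjusted p = 0.691 with an estimated correlation). The number that rose was 5 without any 1 of libraries 3, 8, 13 and 19. NANOG rose from 0.431 ± 0.437 to 11.8 ± 7.97 CPM (log2 fold change 4.79, SE 0.96, adjusted p = 0.0021), with overlap between the libraries of the 2 days. FGF4, a growth factor gene of stem cells, rose from 0.293 ± 0.331 to 4.32 ± 1.54 CPM. LEFTY2, a NODAL antagonist gene, stood at 11.8 ± 9.72 CPM against no count at day 15, at least 330-fold higher. Levels of 134 genes with at least 20 CPM at day 0 and 20-fold less at day 15 were taken as a percent of their day 0 mean. The median was 1.33 to 4.26 in the day 15 libraries. It was 1.92, 7.67, 7.18 and 17.2 in libraries 4, 9, 14 and 19 of day 25. At day 35 it was 2.98, 9.2 and 35.3 in libraries 5, 15 and 20. Library 4 of day 25 and library 5 of day 35 thus lay within the day 15 range. Without libraries 19 and 20 together, left out after the data were seen, 9 pluripotency genes rose and 3 fell.

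**Figure D2:**
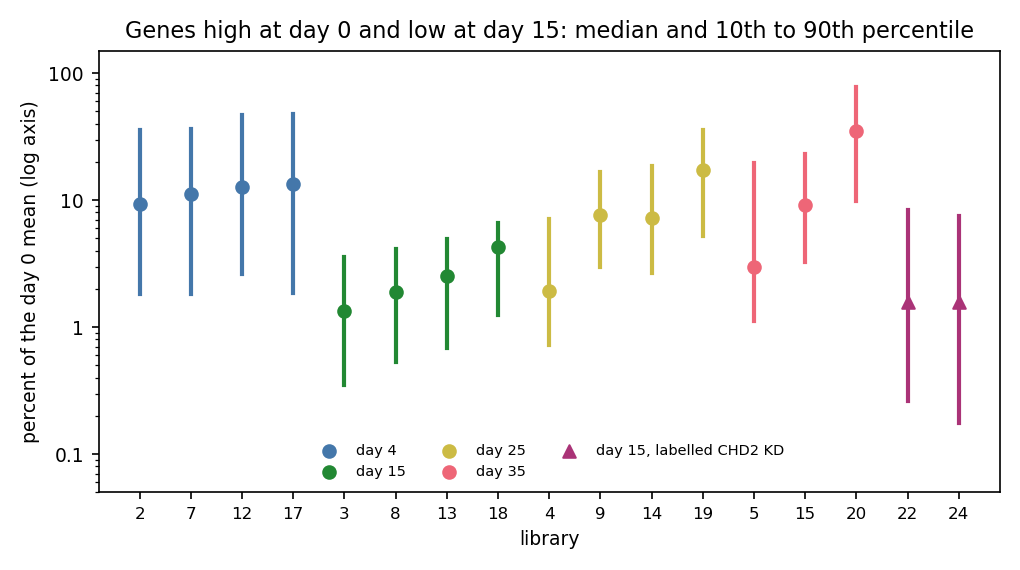
Levels of the 134 genes that were high at day 0 and low at day 15, as a percent of their day 0 mean on a log axis, in each later library; points are medians over the genes and bars run from the 10th to the 90th percentile. The medians lie between 1.33 and 4.26 at day 15, rise to 17.2 in library 19 of day 25 and 35.3 in library 20 of day 35, and are 1.59 and 1.57 in libraries 22 and 24, labelled CHD2 knockdown.

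The largest rises to day 25 also held FIBIN, from 0.183 ± 0.124 to 24.2 ± 8.96 CPM (log2 fold change 6.96, SE 0.5, adjusted p = 1.2e-07), and the collagen gene COL6A3, from 0.107 ± 0.0995 to 15.3 ± 11.4 CPM. The largest falls included OLIG3, a dorsal progenitor factor, from 7.76 ± 1.47 to 0.836 ± 0.752 CPM (-3.20, SE 0.61, adjusted p = 0.0014). GPR50, an orphan receptor gene of the hypothalamus, fell from 262 ± 94.9 to 34.5 ± 10.9 CPM and RAX from 76.3 ± 26 to 10.7 ± 3.94 CPM. Of the 3609 genes called, 2346 rose and 1263 fell, and 2141 changed at least 2-fold.

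From day 25 to day 35 most genes of the synapse list rose, as did single genes of other classes picked by the naming rule. SST rose from 9.63 ± 3.62 to 301 ± 227 CPM (log2 fold change 4.97, SE 0.55, adjusted p = 5.1e-05). UTS2, the urotensin 2 peptide gene, rose from 0.102 ± 0.0393 to 53.1 ± 9.77 CPM (8.94, SE 0.41, adjusted p = 1.4e-10). GRIN2B, an NMDA receptor subunit gene, rose from 11 ± 3.31 to 81.1 ± 34.8 CPM (2.89, SE 0.39, adjusted p = 0.00027). SCN1A, a voltage-gated sodium channel gene, rose from 6.41 ± 1.94 to 25.7 ± 4.86 CPM (2.01, SE 0.34, adjusted p = 0.001). GAD1 rose from 25 ± 10.5 to 122 ± 67.1 CPM (2.29, SE 0.4, adjusted p = 0.0015). HIST1H4B, a replication-dependent histone gene, fell from 109 ± 4.81 to 25.4 ± 13 CPM (-2.10, SE 0.29, adjusted p = 0.00029).

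This step had the least stable calls. Of 3232 genes called, 1818 rose and 1414 fell, and 1745 changed at least 2-fold. Fitted without the other days, days 25 and 35 gave 94 called genes. The number was 1387 without library 15, 1823 without library 9 and 4499 without library 20. Of the genes named for this step, UTS2, SST, DCN, MMP7, ANKRD1, CDKN2B, GRIN2B, TH, EOMES, SLC17A6, SCN1A, TRH, SCG2, HIST1H4B and HIST1H3D were called under both fits. The other genes said to have risen or fallen in this step were not called with the days fitted alone, as for GAD1 (log2 fold change 2.27, adjusted p = 0.0741).

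Synapse genes rose in 18 of 28 cases and 10 were not called (21 rose adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), or 11 without library 9 and 9 without library 5. SYN1, a synaptic vesicle phosphoprotein gene, rose from 5.86 ± 2.8 to 20.7 ± 6.21 CPM. In the epilepsy gene list 15 of 42 rose and 27 were not called (24 rose adjusted over the list alone; adjusted p = 0.312 with an estimated correlation), 25 without library 20. Of 13 GABA receptor subunit genes 7 rose and 6 were not called (13 rose adjusted over the list alone; adjusted p = 0.278 with an estimated correlation), 4 without library 5, 11 without library 4 and 11 without library 20. GABRB1 rose from 2.19 ± 0.454 to 7.43 ± 3.55 CPM. Of 22 pan-neuronal genes 10 rose and 12 were not called (14 rose adjusted over the list alone; adjusted p = 0.428 with an estimated correlation), 4 without library 5 and 6 without library 15. SCG2, a secretory granule protein gene, rose from 62.6 ± 10.1 to 313 ± 40.7 CPM (log2 fold change 2.32, SE 0.21, adjusted p = 5.1e-06). The cortical interneuron list had 10 of 28 genes higher and 2 lower (11 and 2 adjusted over the list alone; adjusted p = 0.452 with an estimated correlation), 6 higher without library 15. LHX6 rose from 15.7 ± 8.01 to 45.2 ± 23.9 CPM (1.53, SE 0.4, adjusted p = 0.016), with overlapping libraries and no call without library 15 (1.05, adjusted p = 0.14).

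Single genes of other types of neuron rose in the same step. TH, the rate-limiting enzyme of dopamine synthesis, rose from 5.3 ± 2.75 to 65.7 ± 24.7 CPM (log2 fold change 3.63, SE 0.52, adjusted p = 0.00034). SLC17A6, a vesicular glutamate transporter gene, rose from 1.26 ± 0.398 to 8.59 ± 3.22 CPM. TRH, the hypothalamic releasing hormone gene, rose from 3.65 ± 0.509 to 21.8 ± 6.68 CPM. In the hypothalamus list 7 of 15 genes rose and 8 were not called (8 rose adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), 4 without library 15. The replication-dependent histone list had 16 of 17 genes lower and 1 not called, also adjusted over the list alone (adjusted p = 0.235 with an estimated correlation). The MGE list had 5 of 20 genes lower and 1 higher, also adjusted over the list alone (adjusted p = 0.778 with an estimated correlation), with 2 lower without library 9, 3 without library 5 and 1 without library 15. In the cell cycle list 5 of 27 genes fell and 22 were not called (6 fell adjusted over the list alone; adjusted p = 0.452 with an estimated correlation), 25 without library 20. Of the histone genes HIST1H3D fell from 161 ± 25.1 to 44.3 ± 19.8 CPM. The p53 response list had 9 of 16 genes lower and 7 not called (11 lower adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), 5 without library 14 and 5 without library 5. MDM2, the ubiquitin ligase that restrains p53, fell from 260 ± 88.8 to 114 ± 33.5 CPM. Among the largest falls were the matrix metalloproteinase gene MMP7, from 25.2 ± 23.7 CPM to 1 count in all (ratio 1430, counting interval 256 to 56500), and ANKRD1, from 465 ± 371 to 18.9 ± 0.613 CPM (-4.62, SE 0.83, adjusted p = 0.0017).

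**Figure D3:**
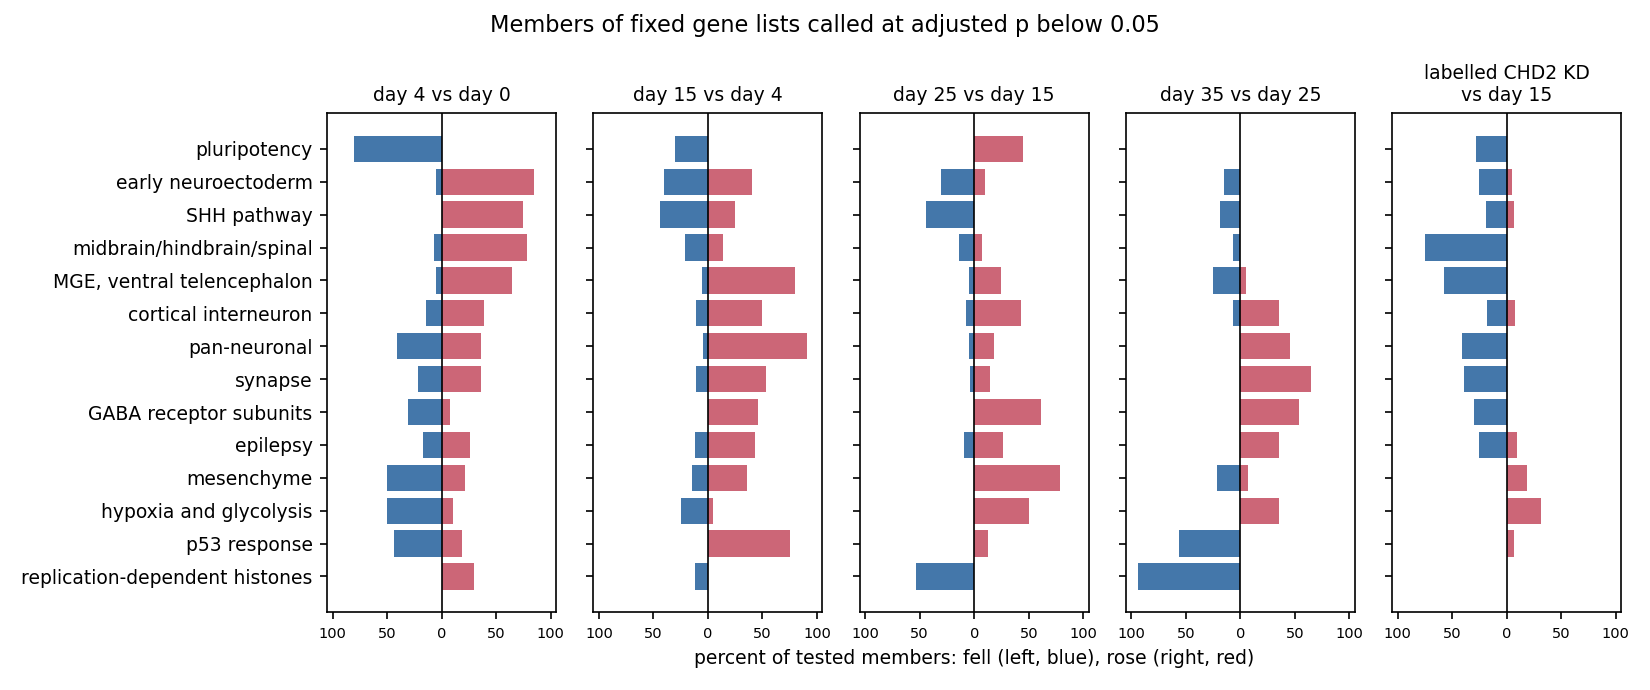
Percent of the tested members of 14 fixed gene lists that rose (right, red) or fell (left, blue) at adjusted p below 0.05 in each of the 5 RNA comparisons. Pluripotency genes fell at day 4 and 9 of 20 rose at day 25, pan-neuronal genes rose at day 15, and 11 of 19 tested MGE genes fell in the libraries labelled CHD2 knockdown.

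NKX2-1 (ENSG00000136352; chromosome 14, 36516397 to 36520232, build hg38) was at 0.217 ± 0.108 CPM at day 0, 45.8 ± 12.7 at day 4, 316 ± 69.4 at day 15, 245 ± 98.7 at day 25 and 138 ± 75 at day 35. Neither step after day 15 passed edgeR's test (log2 fold change -0.37, adjusted p = 0.5 from day 15 to day 25, and -0.82, adjusted p = 0.15 from day 25 to day 35). Every day 35 library (53 to 194 CPM) still lay below every day 15 library (257 to 416 CPM). The contrast of day 35 with day 15 is not reported here for NKX2-1. CHD2 (ENSG00000173575; chromosome 15, 92900324 to 93027996) rose from 122 ± 13.5 to 200 ± 16.7 CPM at day 4 (0.73, SE 0.13, adjusted p = 0.00017) and stood at 252 ± 18 CPM at day 15. At day 25 CHD2 was at 193 ± 31.1 CPM (-0.39, SE 0.13, adjusted p = 0.05), a difference at the threshold. It was not called without any 1 of libraries 3, 8, 9, 13, 14, 18 and 19 (adjusted p from 0.054 without library 9 to 0.14 without library 14).

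**Figure D4:**
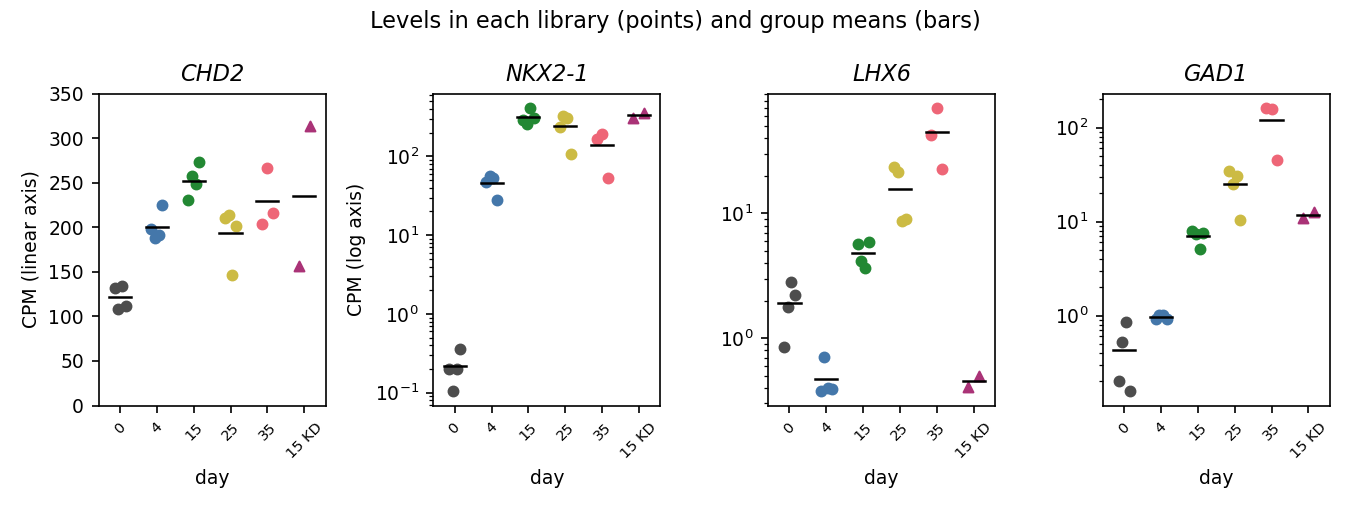
Levels of CHD2 (linear axis) and of NKX2-1, LHX6 and GAD1 (log axes) in CPM, with a point for each library, bars at group means, and triangles for the libraries labelled CHD2 knockdown (15 KD). CHD2 is at 157 CPM in library 22 and 314 CPM in library 24, on either side of the 4 day 15 libraries, and LHX6 is below 1 CPM in both.

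The binding data addressed which genes NKX2-1 occupied in day 15 cells. The 4867 peaks lay on 23 chromosomes and were 51 to 933 bases wide, with a median of 230 bases. Of these, 2449 (50.3%, Wilson 95% interval 48.9 to 51.7) fell inside the span of a protein-coding gene, against 44.1% (range 42.6 to 45.6) over 100 random placements. Of the peaks 15.3% lay within 1 kb of either boundary of a protein-coding gene span, starts and ends pooled, against 2.7% (2.1 to 3.4) at random. Random positions were drawn evenly between the first and last peak of each chromosome. Stretches where no peak can be called were not left out, so both random shares may be too low. NKX2-1 itself held a peak at chromosome 14, 36516829 to 36517001, inside its span. A peak at chromosome 15, 92899931 to 92900256, lay 68 bases outside the span of CHD2, and SOX6, a factor of MGE interneurons, held a peak at chromosome 11, 16095933 to 16096158, inside its span of 15966449 to 16738477. The nearest peak to LHX6 lay 108783 bases away, to DLX1 150765 bases, to LHX8 435377 bases and to SHH 802259 bases. WWOX, NPAS3 and ZFHX3 were each the nearest gene of 8 peaks, AUTS2, DLGAP1 and NAV2 of 7, and SOX2, a neural progenitor factor, and TCF7L2 of 6.

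A gene was counted as a peak gene when it was the nearest protein-coding span within 50 kb of a peak, which gave 2900 of 15141 tested genes (19.2%). In the list of lateral and caudal ganglionic eminence genes 9 of 17 were peak genes, among them the transcription factors MEIS2, SP8, NR2F2 and FOXP2. In the radial glia list 10 of 19 were peak genes, including FABP7, HES1 and NES, and in the early neuroectoderm list 10 of 20, including LHX2, OTX2 and SIX3. The MGE list had 6 of 20 (GBX2, NKX2-1, OLIG2, SIX3, SOX6 and ZFHX3) and the SHH pathway list 6 of 16, among them FOXA2, GLI2 and GLI3. There were 10 of 28 in the cortical interneuron list, among them ERBB4, MAF and ZEB2, and 0 of 16 in the p53 response list. These shares per list were not tested.

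Peak genes were more frequent among genes that rose toward day 15. Of the peak genes 23.3% (676 genes) were at least 2-fold higher at day 15 than at day 0, against 17.3% of other genes (odds ratio 1.45, 95% interval 1.32 to 1.6, Fisher's exact test, adjusted p = 2.17e-12 over 8 tests). For genes lower at day 15 the odds ratio was 0.80 (0.72 to 0.89, adjusted p = 7.3e-05). Of the peak genes 80 (2.8%) were at least 2-fold lower at day 25 than at day 15, against 1.4% of other genes (odds ratio 2.04, 1.56 to 2.67, adjusted p = 2.08e-06), and for genes higher at day 25 the odds ratio was 1.26 (1.1 to 1.44, adjusted p = 0.00124). Peak genes were longer, with a median span of 73.5 kb against 27.6 kb. With gene length, mean expression and distance between neighbours as covariates, the odds ratios for genes lower at day 15 (0.93, adjusted p = 0.32) and higher at day 25 (1.07, adjusted p = 0.443) were no longer past the threshold.

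**Figure D5:**
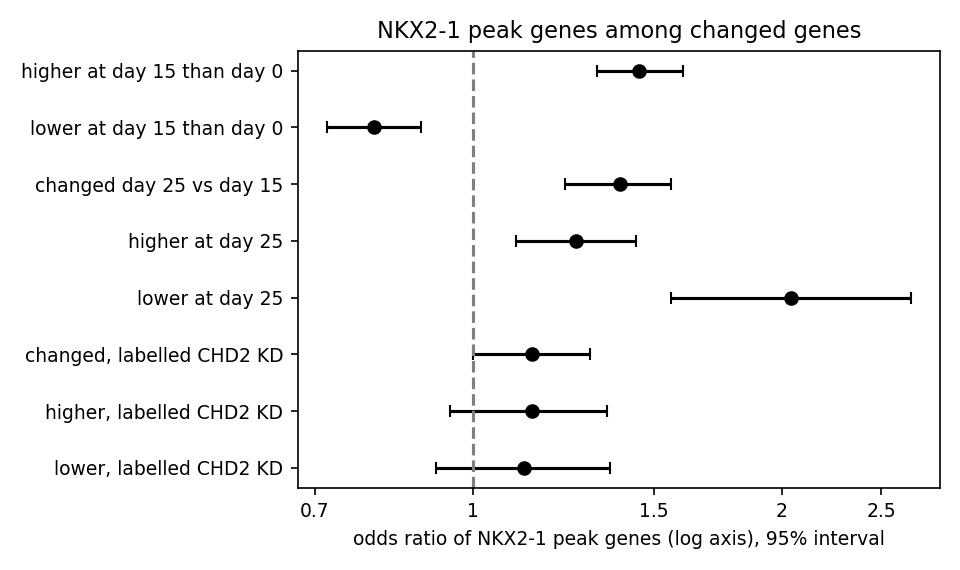
Odds ratios (points, log axis) with 95% intervals for NKX2-1 peak genes among genes of each class, Fisher's exact test over 15141 genes for the time course and over 14183 genes for the libraries labelled CHD2 knockdown; the dashed line marks an odds ratio of 1. The odds ratio is 1.45 for genes higher at day 15 than day 0, 2.04 for genes lower at day 25 and 1.14 for genes changed in the libraries labelled CHD2 knockdown.

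The knockdown comparison addressed which genes depend on CHD2 in day 15 cells. CHD2 itself stood at 157 CPM in library 22 and at 314 CPM in library 24, both labelled CHD2 knockdown, against 230 to 273 CPM (252 ± 18) in the 4 day 15 libraries. Relative to these day 15 libraries its transcript thus went against the label in library 24, and the fitted difference did not pass the test (log2 fold change -0.09, SE 0.27, adjusted p = 0.86). The changes below are those of the libraries labelled CHD2 knockdown relative to the day 15 libraries, and do not follow from the CHD2 transcript level alone. Library 24 also stood apart in the makeup of its RNA. MALAT1, a nuclear non-coding RNA, held 2.32% of its counts, against 0.29% in library 22 and at most 0.979% in a time course library, and long intergenic RNAs held 2.97%. Of 19174 genes tested 1775 were called, 949 higher and 826 lower, and 1323 changed at least 2-fold. With library sizes that left out mitochondrial genes and genes above 1% of counts, and without TMM factors, 754 were higher and 1078 lower of 1832. The higher share went from 53.5% to 41.2% (median shift -0.10 on the log2 scale). Over all 21 libraries the TMM factors were 0.923 and 1.004 in libraries 22 and 24, against 1.006 to 1.085 at day 15. Whether the genes left out or the missing factors moved the share was not tested.

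In the libraries labelled CHD2 knockdown most of the MGE list and a smaller part of the cortical interneuron list were lower. LHX6 fell from 4.86 ± 1.15 to 0.452 ± 0.0661 CPM (log2 fold change -3.41, SE 0.41, adjusted p = 0.0031). DLX6, the gene next to DLX5 in the same homeobox family, fell from 2.23 ± 0.87 to 0.198 ± 0.0339 CPM (-3.46, SE 0.62, adjusted p = 0.013). DLX5 fell from 1.94 ± 0.453 to 0.115 ± 0.0837 CPM (-4.03, SE 0.58, adjusted p = 0.0057). GAD2, which encodes the GABA-synthesizing enzyme GAD65, fell from 7.66 ± 1.9 to 1.43 ± 0.685 CPM (-2.44, SE 0.4, adjusted p = 0.0089). NKX2-1 stood at 332 ± 39.1 against 316 ± 69.4 CPM (0.07, adjusted p = 0.88) and GAD1 at 11.8 ± 1.4 against 7.01 ± 1.32 CPM (0.74, adjusted p = 0.11).

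In the MGE list 11 of 19 genes fell in the libraries labelled CHD2 knockdown and 8 were not called, also adjusted over the list alone (adjusted p = 0.235 with an estimated correlation), 7 without library 8. Of 27 cortical interneuron genes 5 fell, 2 rose and 20 were not called (7 and 2 adjusted over the list alone; adjusted p = 0.452 with an estimated correlation), 8 lower without library 24. Those that rose were NXPH2, from 5.21 ± 0.862 to 12 ± 2.38 CPM, and CXCR4, from 29.3 ± 6.1 to 57.3 ± 17.8 CPM. Neither NXPH2 (adjusted p from 0.058 to 0.076) nor CXCR4 (0.057 to 0.11) was called without any 1 of libraries 3, 8, 13 and 18, nor was CXCR4 without library 24 (0.1). Of 22 pan-neuronal genes 9 fell and 13 were not called (15 fell adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), 4 without library 3, 4 without library 8, 4 without library 18 and 17 without library 22. ISL1 fell from 13.7 ± 2.25 to 2.29 ± 1.51 CPM (log2 fold change -2.60, SE 0.4, adjusted p = 0.0072). ELAVL3, a neuronal RNA-binding protein gene, fell from 55.6 ± 3.33 to 18.4 ± 0.0502 CPM. Of 28 synapse genes 11 fell and 17 were not called (15 fell adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), 6 without library 3, 7 without library 8, 6 without library 18 and 17 without library 22. UNC13A, a vesicle priming gene, fell from 40.2 ± 7.05 to 10.3 ± 0.602 CPM (-1.97, SE 0.23, adjusted p = 0.0025). BSN, the active zone scaffold bassoon, fell from 44.4 ± 10.6 to 11.7 ± 0.204 CPM. The midbrain, hindbrain and spinal cord list had 6 of 8 genes lower and 2 not called (7 lower adjusted over the list alone; adjusted p = 0.235 with an estimated correlation), 3 without library 3 and 2 without library 8. PAX8, a midbrain-hindbrain boundary gene, fell from 2.69 ± 0.734 to 0.253 ± 0.112 CPM.

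The epilepsy list, which holds CHD2, had 11 of 43 genes lower and 4 higher (12 and 4 adjusted over the list alone; adjusted p = 0.381 with an estimated correlation). Without library 3, 6 were lower and 2 higher, and without library 8, 6 were lower. PLCB1, a phospholipase gene, rose from 6.48 ± 1.45 to 64.1 ± 21.8 CPM (log2 fold change 3.30, SE 0.27, adjusted p = 0.00038). Interferon response genes rose in 4 of 9 cases and 5 were not called (7 rose adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), 2 without library 3, 2 without library 8 and 7 without library 24. OAS3, an antiviral enzyme gene, rose from 0.691 ± 0.148 to 6.45 ± 1.44 CPM (3.19, SE 0.31, adjusted p = 0.0011). COL1A1 rose from 3.55 ± 1.98 to 46.1 ± 16.3 CPM (3.70, adjusted p = 0.0022), and BMP4, a dorsalizing signal gene, rose from 1.89 ± 0.408 to 6.86 ± 1.86 CPM.

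The largest differences were close to on and off. ZBED6CL stood at 9.98 ± 2.11 CPM in the libraries labelled CHD2 knockdown against no count in the day 15 libraries, at least 259-fold higher. LRRC61, whose locus overlaps it so that reads of the pair could be shared, rose from 0.0567 ± 0.041 to 18.3 ± 1.25 CPM (log2 fold change 8.12, SE 0.43, adjusted p = 4.5e-05). The zinc finger gene ZNF248 went from 30.1 ± 1.86 CPM to 1 count (ratio 1150, counting interval 206 to 45300) and CAT, the antioxidant enzyme catalase, from 39.9 ± 5.84 CPM to 2 counts (769, 213 to 6350). ZNF680 went from 37.3 ± 6.03 CPM to 2 counts (707, 196 to 5840). NNAT, an imprinted gene, fell from 2850 ± 1090 to 7.15 ± 2.74 CPM (-8.63, SE 0.59, adjusted p = 0.00014). Of 18893 protein-coding genes with a single ID, 10 were on in both libraries labelled CHD2 knockdown and off in all 19 time course libraries or the reverse, and the highest number for any of 27 pairs of libraries of 1 day, set against the libraries of the other days, was 4. The number of called genes was 587 without library 3, 604 without library 8, 819 without library 18, 2902 without library 24 and 4608 without library 22. In the last 2 of these, as wherever library 22 or 24 is left out, the labelled group is a single library and the spread comes from the day 15 libraries alone, so these counts say nothing about stability.

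Changes in the libraries labelled CHD2 knockdown ran against those from day 4 to day 15 across 18990 genes, which are not independent replicates (Pearson r -0.28, Spearman -0.32, covariance -0.27). Unchanged groups, with every library simulated from the day 15 means and day 15 shared by both comparisons, gave r -0.40 and covariance -0.05. Mean log2 CPM differences with the day 15 libraries split between the comparisons gave r -0.30 to -0.23 and covariance -0.24 to -0.19 over 6 splits. Library 24 carried most of this, with r -0.39 and covariance -0.38 alone against -0.13 and -0.11 for library 22 alone, both from mean log2 CPM differences. NKX2-1 peak genes among the changed genes had an odds ratio of 1.14 (95% interval 1.0 to 1.3, Fisher's exact test, adjusted p = 0.0839), with 1.14 for those higher (0.95 to 1.35, adjusted p = 0.174) and 1.12 for those lower (0.92 to 1.36, adjusted p = 0.243). Without library 24 the odds ratio of those lower was 1.64, from genes called in library 22 alone with the spread of the day 15 libraries.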

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

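The tests of the 3 weighed patterns were chosen after the results were seen, while the counts of other splits of the libraries and the comparison of each library with its group were planned.

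The libraries of days 25 and 35 differed in their levels of genes high at day 0 and low at day 15. Day 0 RNA or reads mixed into a library would leave no such gene far below the share of its day 0 level that the median rise over day 15 needs. In libraries 19 and 20 the shares needed were 12.5 to 37.3%. With each day 0 library as the source, 11.6 to 15.8% of the genes in library 19 lay under 0.5 times that level. In library 20 it was 16.4 to 19.9%, and between 2 day 0 libraries at most 8.1%. No interval was taken, and the margin in library 19 is narrow, so mixing as the whole source stays open there. In library 20 the values argue against it. For the other libraries of these days the percent was 3.0 to 13.6, so mixing cannot be told apart there from other sources. A stage change shared by every culture may account for part of it. With genes chosen from the other runs of library numbers, the median was higher at day 25 than at day 15 in 4 of 4 runs (1.32 to 4.12-fold) and higher at day 35 than at day 25 in 3 of 3 (1.25 to 2.0-fold). The lowest of these lies no higher than the day 0 spread of 1.25-fold, so a shared change cannot be told apart from differences between libraries, which spread 8.98-fold at day 25 and 11.9-fold at day 35. A difference between the runs may account for the spread: the run of libraries 1 to 5 was lowest and that of libraries 16 to 20 highest on all 3 days in 6 of 6 settings, which a share of 0.0139 of the orders at days 25 and 35 gives by chance. In 5 of the 6 settings the full order of day 15 was found again on both later days. In the setting used here it was found at day 35 and not at day 25, where the reversal of 1.07-fold lies within the day 0 spread. What the runs stand for is not given in the sources used here. Persisting undifferentiated cells in some cultures are a biological explanation. With an unchanged day 0 profile they would add day 0 RNA as mixing does, so in library 20 the same values argue against them as the whole source. Persisting cells whose profile had changed were not tested and stay open, as do persisting cells in the other libraries, library 19 among them.

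Genes whose symbol belongs to several IDs had low counts, and this limits POU5F1 among the genes named. If reads shared between copies were lost in counting, such genes would be low wherever they lie, and outside the copy-rich region of chromosome 6 (29000000 to 34000000) 81.7% of them (423 of 518) were under 1 CPM, against 24.3% (4177 of 17155) of symbols with a single ID (odds ratio 13.8, Fisher's exact test, p = 4.55e-160). That the genes are silent in these cells cannot be told apart from loss by ribosomal protein genes, of which 4 have several IDs and 1 was under 1 CPM (RPS18 at 0.137 CPM, with RPL41 at 329 CPM the highest), against 2 of 80 with a single ID, whose median was 357 CPM. Loss of shared reads and silent genes both stay open, since the low share outside that region goes with either.

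The libraries labelled CHD2 knockdown differ from day 15 in ways that the CHD2 transcript does not follow. Relative to the day 15 libraries (230 to 273 CPM), CHD2 transcript was lower in library 22 (157 CPM) and not in library 24 (314 CPM). Without a control of the same cells, neither value shows whether CHD2 transcript was lowered by a knockdown. Cells of another origin than the time course may contribute, since 22 of 2636 gene copies with shared symbols were switched on or off in this pair against at most 3 in any of 27 pairs of libraries of 1 day set against the other days. An earlier stage of differentiation may contribute too, but these values cannot tell it apart from other changes. The covariance with the step from day 4 to day 15 was at most -0.19 over 6 splits of the day 15 libraries. Simulated unchanged groups gave -0.05, but their day 4 was also drawn from the day 15 means, so an unrelated change was not simulated. Most of the covariance came from library 24 (-0.38 alone, without a split, against -0.11 for library 22). LHX6 was near its day 4 level (0.452 against 0.469 CPM). NKX2-1 (332 against 45.8 CPM) and GAD1 (11.8 against 0.963 CPM) were far above theirs. In the comparison made here, the effect of a knockdown, the origin of the cells and the culture or vector are joined in the same libraries. The 2 count columns whose headers say non target control were not used, and whether they would separate these was not examined. The biological explanation, loss of CHD2 function, stays open and untested.

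For each step of the time course, 1 of the 35 splits of the libraries, the real one, gave as many called genes when the 2 days were fitted alone. The real counts were 11423, 9272, 2521 and 94 from the first to the last step and the highest other was 0. The other splits mix both days in each group, so few calls are likely there once the days differ. A share of 1 in 35 is under 0.05 for each step only where libraries of 2 days can be exchanged freely. For the last step it concerns the 94 genes of that fit and not the 3232 called in the fit over the whole time course. With swaps kept within the runs of library numbers there are 8 splits, or 4 for the last step, too few for a share under 0.05.

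Each group of 4 libraries was searched for 39 quantities, 156 tests in all. In 14 of them a library lay far from the others, where chance gives 7.8, about 1 in 20. The tests share libraries and are not independent, so the excess over 7.8 decides nothing. At day 4 library 7 stood apart for LHX6 at 0.713 CPM (others 0.375 to 0.399) and library 2 for POU5F1 at 0.0535 CPM (others 0). These are 12 counts against 6 to 9 for LHX6 and 1 count against 0 for POU5F1, differences that counting error alone can give. Other such values were list means of log2(CPM + 1). At day 4 library 17 had 5.63 for autism genes (others 5.42 to 5.43), 2.14 for cortical interneuron genes (2.45 to 2.5), 1.34 for dorsal telencephalon genes (1.6 to 1.64), 2.01 for hypothalamus genes (2.11 to 2.13) and 4.39 for synapse genes (4.11 to 4.15), and library 2 had 7.31 for cell cycle genes (7.47 to 7.48). At day 15 library 13 had 5.6 for autism genes (5.77 to 5.8). At day 25 library 14 had 6.68 for CHD family genes (7.2 to 7.27) and 3.99 for SHH pathway genes (4.49 to 4.54), library 19 had 2.17 for choroid plexus genes (2.65 to 2.74) and library 4 had 5.38 for NOTCH genes (5.29 to 5.3). At day 0 library 1 had 3.0 for oligodendrocyte genes (3.22 to 3.25).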

How the results depend on the processing

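The fits without libraries 19 and 20, with the runs of library numbers as a term, and without genes of several IDs were chosen after the results were seen. Also not planned were the wider peaks, and leaving out libraries for the odds ratios and for the day of highest expression. The rest were planned. With a 2-fold minimum the 4 steps of the time course called 6181, 4248, 2141 and 1745 genes. At an adjusted p below 0.01, day 15 against day 4 called 4773, day 25 against day 15 called 1684, day 35 against day 25 called 1103 and the libraries labelled CHD2 knockdown 410. Fitted alone, days 25 and 35 gave 94, which has fewer residual degrees of freedom, and without the low-count filter the libraries labelled CHD2 knockdown gave 2874. With libraries 19 and 20 left out the steps called 11724, 8818, 4697 and 3940 genes, and with runs as a term 11388, 8512, 4734 and 3953. DESeq2 called 11090, 7884, 4156 and 3892, and 2619 for the libraries labelled CHD2 knockdown, which had 1654 without genes of several IDs or on-off genes and 1993 in a fit over 21 libraries. List tests called 0 with an estimated correlation and 141 by fry in either direction.

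Leaving out each library in turn gave 9379 to 10159, 6015 to 6691, 2555 to 3627 and 1387 (without library 15) to 4499 (without library 20) genes for the 4 steps, and 587 (without library 3) to 4608 (without library 22, which leaves a labelled group of 1) for the libraries labelled CHD2 knockdown. It gave 71 to 80 list calls, 5398 to 5861 genes highest at day 0, odds ratios for genes of the libraries labelled CHD2 knockdown of 1.09 to 1.2 (changed), 0.92 to 1.28 (higher) and 0.98 to 1.64 (lower), and a correlation with the step from day 4 to day 15 of -0.38 to -0.11. With no distance limit the odds ratios for the libraries labelled CHD2 knockdown passed the threshold, at 1.23 (adjusted p = 0.00177), 1.21 (higher, 0.0299) and 1.23 (lower, 0.0315). With the peaks above the median width those for changed (1.24, 0.0181) and higher genes (1.28, 0.0303) did so and that for genes higher at day 25 did not (1.11, 0.225). With covariates, genes lower at day 15 (0.93, 0.32) and higher at day 25 (1.07, 0.443) did not pass. The cause of these shifts was not tested. Of 9126 values of named genes under other settings, 8232 kept their direction and side of the threshold, 884 lost the call, 10 gained it and 0 reversed. Calls held under all settings for 142 of 162 named genes at day 4, 126 of 162 at day 15, 95 of 136 at day 25, 15 of 109 at day 35 and 35 of 95 in the libraries labelled CHD2 knockdown. No paired analysis was possible because the columns carry no replicate numbers of the labels. The runs are a block by library number instead, and the deviations of libraries of 1 run correlated at 0.03 to 0.139 between days 0 and 4, 0.009 to 0.31 between days 4 and 15, 0.118 to 0.444 between days 15 and 25 and 0.158 to 0.66 between days 25 and 35. With runs as a term, the GABA receptor genes higher at day 35 went from 7 to 12 and the hypoxia and glycolysis genes from 7 to 11. Without libraries 19 and 20, those of GABA receptors were 11, and the cell cycle genes lower at day 35 went from 5 to 23. A stricter peak signal, ranking of peaks by signal and the nearest transcription start were not run. Depth limits the genes at 0 to 3 counts, where ratios have wide intervals, and a 2-fold change was recovered in 32 to 64% of simulated genes.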

Other observations

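The gene lists below were fixed before the results were seen and no test here was chosen afterwards, apart from the genes picked out for single sentences.

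Genes of other forebrain and ventricular tissues moved alongside those already described. In the choroid plexus and roof plate list 7 of 11 genes rose by day 4 and 4 were not called (7 adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), and at day 25 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.368 with an estimated correlation). TTR, the thyroid hormone carrier made by choroid plexus, rose from 7.54 ± 3.75 to 57.3 ± 44.6 CPM at day 25 (log2 fold change 2.92, SE 0.68, adjusted p = 0.0066), with overlapping libraries. In the list of lateral and caudal ganglionic eminence genes 10 of 17 rose by day 4 and 3 fell, also adjusted over the list alone (adjusted p = 0.462 with an estimated correlation), among them MEIS2, a homeobox gene of the lateral eminence, which reached 21.3 CPM, and against them SP8, which fell to 1.66 CPM. The cholinergic and subpallial list had 9 of 13 genes higher at day 15 and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.392 with an estimated correlation). ZIC1 rose from 6.37 ± 3.4 to 247 ± 87.9 CPM (5.27, SE 0.52, adjusted p = 6.4e-07), and the gene that fell was the neurotrophin receptor gene NGFR, to 31.5 CPM. CHAT, which makes acetylcholine, rose from 0.72 ± 0.323 to 3.04 ± 1.15 CPM at day 35 (2.07, SE 0.34, adjusted p = 0.00081).

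Some genes of the hypoxia and glycolysis list, part of which fell at day 4, rose later. At day 25 10 of 20 rose and 10 were not called (15 rose adjusted over the list alone; adjusted p = 0.428 with an estimated correlation), 5 without library 3, 6 without library 18 and 6 without library 14. EGLN3, an oxygen sensor of the HIF pathway, rose from 12.8 ± 0.8 to 33.9 ± 12.8 CPM (SE 0.26 on the log2 scale, adjusted p = 0.001). At day 35 a further rise held for 7 of 20 (15 adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), 11 without library 14 and 4 without library 15, with ENO2, a glycolytic enzyme of neurons, going from 197 ± 49.4 to 552 ± 130 CPM. In the libraries labelled CHD2 knockdown 6 of 19 rose against day 15 (14 adjusted over the list alone; adjusted p = 0.525 with an estimated correlation), 1 without library 3, 1 without library 8, 2 without library 18, 16 without library 22 and 3 without library 24. In the mesoderm and endoderm list 5 of 16 genes rose at day 35 and 11 were not called (6 rose and 1 fell adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), 10 without library 5. Of its members APOA1 rose from 1.12 to 15.7 ± 11.2 CPM (adjusted p = 0.00042) and outside the list APOA2, another lipoprotein gene, rose from 0.0751 to 7.82 ± 7.05 CPM (6.57, SE 0.92, adjusted p = 0.00032), and neither was called with days 25 and 35 fitted alone.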
